A study of Homo sapiens with 6 samples.

How the data were processed

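Gene expression was measured by RNA sequencing in LX-2 cells, an immortalised human hepatic stellate cell line. Per the labels, the cells grew in medium with 2% fetal bovine serum, were kept without serum for 18 h, and then received 100 ng/mL of IGFBP-7 protein or phosphate-buffered saline (PBS) for 24 h. Libraries were made from poly(A) RNA with a directional kit, NEBNext Ultra II, and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. There were 3 libraries per group, assigned to PBS or IGFBP-7 from the treatment label of each sample. No label states that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

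The deposited table gives 1 value per gene and library for 16569 genes. Per the file headers these are normalized counts, a signal that the authors obtained from read counts and did not log-transform. STAR, Subread, featureCounts and DESeq2 are named, without version or role, per the submitters' processing notes. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, and for that reason no coordinates are printed. The table pairs each gene symbol with an Ensembl identifier and a gene type, and these were used as they stand: 12731 genes were protein coding, 3690 were long noncoding RNA genes and 148 were of other types. Genes at 0 in all 6 libraries numbered 0. Per-sample columns left unused numbered 0.

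Within each library every value was a whole multiple of 1 step, so the authors' read counts could be recovered: 100% of the values came out whole within 0.01 of a step. Of the nonzero recovered counts, 99.6% were even in each library, and 2 reads were taken as 1 sequenced fragment. The PBS libraries hold 41345077, 43537923 and 40599380 recovered reads on the genes of the table and the IGFBP-7 libraries 47196478, 55479940 and 45242993, in the order of replicates 1 to 3. A level of 3 fragments in 1 library corresponds to 2.54 to 3.20 normalized counts, which is the level under which a gene cannot be told from absent in that library. Intervals and this floor cover counting error only, as reads without molecular identifiers are not independent molecules. Libraries of a group were compared with a chi-square test of their fragments over genes: chi-square per degree of freedom was 5.27 to 7.23 for the 6 pairs, so no pair agreed within sampling noise and all 6 libraries were counted.

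The design set before the data were examined named edgeR for raw counts and limma for normalized values. As the deposited values are normalized, the comparison was made with limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), IGFBP-7 minus PBS, over all 6 libraries and without covariates. The 11872 genes with a mean of at least 10 normalized counts over the 6 libraries were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Of these, 9852 were protein coding and 1926 were long noncoding RNA genes. A log2 change here is on the log2(normalized count + 1) scale, which understates the change of genes at low level, and folds are these changes on the linear scale. Each is given with limma's standard error (SE), and levels are means of normalized counts over the 3 libraries of a group with their SD.

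Before the data were examined, 29 gene lists were fixed: stellate activation, stellate quiescence, collagens, matrix glycoproteins and proteoglycans, matrix remodelling enzymes and inhibitors, TGF-beta response, IGF axis, cytokines and chemokines, NF-kappaB response, secreted growth factors, interferon response, proliferation, p53 response and cell-cycle arrest, immediate early and MAPK feedback, YAP and TEAD response, mesenchymal transition regulators and junctions, unfolded protein and integrated stress response, cholesterol synthesis, fatty acid synthesis and lipid storage, hypoxia and glycolysis, oxidative phosphorylation, NRF2 and antioxidant response, markers of hepatocytes, of endothelial cells, of macrophages and leukocytes and of epithelial cells and cholangiocytes, cytosolic ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. Older symbols were matched through the RefSeq synonyms. Each list with at least 5 tested members, 27 in all, was tested against the other tested genes with camera (cameraPR in limma) on the moderated statistics, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 27 lists. Members rising, falling and not passing were counted over all genes tested and also adjusted over the list alone. The lists were also run with the correlation between members estimated per list, and with fry, which asks whether the genes of a list move on balance one way.

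Genes were named by a rule fixed before the data were examined. IGFBP7 is always named. Among genes with an adjusted p under 0.05, no overlap between the groups, a gene symbol that is not of a clone or identifier type and a mean of at least 50 normalized counts, the rule takes the 10 with the largest rise, the 10 with the largest fall and the 5 with the smallest p in each direction. From each list it takes up to 4 tested members with the smallest p, and for lists of other cell types or RNA quality also the 2 with the highest mean. A gene that the rule takes is not reported here. A gene named outside this rule is said to have been chosen after its values were seen. For the named genes with under 5 fragments over the 3 PBS libraries (FOXS1, SCN7A and MYOM3), the ratio of fragments per unit of library depth is given with its 95% exact binomial (Clopper-Pearson) interval.

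The steps were tested on simulated data, 5 tables drawn for the comparison of IGFBP-7 with PBS from the PBS means, the libraries' depths and the genes' dispersions, with 11807 to 11834 genes tested and 200 changed by known folds, 50 per fold. The share recovered was 41.2% of the genes changed 1.25-fold, 70.4% at 1.5-fold, 80.8% at 2-fold and 91.6% at 4-fold. Genes wrongly called made up 2.95% of the calls. In tables without any change limma called 0 genes and camera 0 lists, and a shifted list was found in 5 of 5 tables. The genes were drawn independently, so the 0 lists do not test camera where members of a list are correlated. In the real lists the estimated correlation ranged from -0.087 to 0.64. The simulated tables also had only 200 changed genes in balanced directions, against 7192 calls in the data. The recovered and false shares therefore need not carry over.

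The alternatives were quantile normalization, upper-quartile scaling, no filter, a filter at a mean of 100 normalized counts, pseudocounts of 0.1 and 5, DESeq2 1.42.0 and edgeR 4.0.16 on the recovered reads, the replicate number as a block, each library left out in turn, other thresholds and the other list tests. Scaling to the library total and edgeR on recovered fragments were added after the data had been seen. The library total is the sum of the normalized counts over the genes of the table, not over all reads of a library. The table has 0 of 15 listed mitochondrially encoded genes and 13 of 34 listed ribosomal protein genes. The count tests called 6932 genes with DESeq2 and 7135 with edgeR on recovered reads. As 2 reads were taken as 1 fragment, tests on reads count each fragment as 2 and can understate counting error. With edgeR on recovered fragments 7187 genes were called. Other checks used the GENCODE release 29 transcripts for GC content and length. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. List members without a row in the table used here were not analysed here.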

Results

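The series compares LX-2 cells given IGFBP-7 protein with LX-2 cells given PBS, in 3 libraries each. LX-2 is an immortalised line of hepatic stellate cells, the pericytes of the liver that turn into matrix-producing myofibroblasts after injury. IGFBP-7 is a secreted protein of the insulin-like growth factor (IGF) binding protein family. The comparison shows which transcripts of LX-2 cells differ after IGFBP-7. Whether such differences favour hepatocellular carcinoma in metabolic dysfunction-associated steatotic liver disease was not measured, as all samples are LX-2 cells. Levels are the authors' normalized counts, given as mean ± SD over n = 3 libraries per group, and log2 changes are IGFBP-7 minus PBS ± SE from limma-trend. The PBS libraries held 40599380 to 43537923 recovered reads and the IGFBP-7 libraries 45242993 to 55479940, with 2 reads taken as 1 fragment. Correlations between libraries over the tested genes, which are not independent replicates, were 0.987 to 0.989 within groups and 0.952 to 0.954 between groups. The first principal component separated the groups and held 71.0% of the variance, and the second held 8.45%.

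After 24 h with IGFBP-7, 16 of 20 tested collagens and 24 of 27 TGF-beta response genes rose, and 16 of 23 NF-kappaB response genes and 19 of 23 YAP and TEAD response genes fell. FN1, which encodes fibronectin, rose from 102918 ± 4088 to 544971 ± 32799 normalized counts. It had the highest value among the genes of the table in each IGFBP-7 library. SERPINB2, which encodes an inhibitor of plasminogen activators, fell from 8867 ± 584 to 378 ± 29.4. Of the 11872 genes tested, 7192 (60.6%) changed at an adjusted p under 0.05, 3721 higher and 3471 lower with IGFBP-7. Scaling to the library total, taken over the genes of the table, was chosen after the data were seen. It gave 2432 genes higher and 4176 lower, and moved the median log2 change of all tested genes by -0.14. Under this scaling 15 collagens and 20 TGF-beta response genes rose, and 17 NF-kappaB and 19 YAP and TEAD response genes fell. Of the changed genes, 1150 rose and 1551 fell by at least 1.5-fold, 599 rose and 752 fell by at least 2-fold, and 205 rose and 164 fell by at least 4-fold. The groups did not overlap in 7542 genes (63.5%), where chance gives 10%, and 6828 of these were among the changed genes. Protein-coding genes made up 6497 of the changed genes and long noncoding RNA genes 670. The 10 genes with the highest values in a library took 4.49% to 4.66% of its normalized counts in PBS and 8.42% to 9.07% with IGFBP-7. These shares are of the counts on the genes of the table.

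The cells' own IGFBP7 transcript rose from 11180 ± 511 to 20740 ± 474, a log2 change of 0.89 ± 0.04 (limma adjusted p = 8.07e-24), with the 3 IGFBP-7 libraries above the 3 PBS libraries. Added protein brings no RNA, so this value is no check of the labels. IGFBP7-AS1, an antisense gene named here after its values were seen, rose along with it from 3610 ± 215 to 6643 ± 216. As the strand setting of the counting is not given in the sources used here, reads of the 2 genes cannot be told apart and both values are uncertain. The same holds for other genes named here that have an antisense gene in the table, namely BDNF, COL5A1, INHBA, LIF, LRRC7, PHLDA1, RARA, SLC7A11, THBS1 and TPM1.

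Of the 10 largest rises under the naming rule, 8 began below 10 normalized counts. FOXS1, which encodes a forkhead transcription factor, was at 1.37 ± 2.38 in PBS and 857 ± 78.2 with IGFBP-7. Its 4 fragments in the PBS libraries against 2664 give a ratio of 623 with a 95% counting interval of 243 to 2289. KANK4, which encodes an ankyrin-repeat protein, rose from 3.48 ± 2.54 to 1370 ± 134, and ODAPH, an enamel matrix gene, from 2.38 ± 0.491 to 457 ± 49.6. SCN7A, a sodium channel gene, was at 1.34 ± 1.16 and 261 ± 27.2, a ratio of 192 with an interval of 74.7 to 706 from 4 PBS fragments. MYOM3, which encodes a sarcomere protein, had 2 PBS fragments against 438, a ratio of 205 with an interval of 56.4 to 1697. PMEPA1, which encodes a TGF-beta-induced membrane protein, rose from 157 ± 24 to 15242 ± 237, a log2 change of 6.60 ± 0.08. The other large rises were in ISLR2 (log2 change 6.25 ± 0.32), the neuropeptide gene GAL (6.02 ± 0.30), CGB8 (5.93 ± 0.47) and the zinc-finger factor gene EGR2 (5.46 ± 0.17). CGB8 shares nearly identical sequence with other chorionic gonadotropin beta genes, and its value is uncertain for that reason.

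Among the largest falls, VCAM1, which encodes an adhesion molecule for leukocytes, went from 3201 ± 188 to 302 ± 21, and PTX3, which encodes a soluble pattern-recognition protein, from 4428 ± 403 to 439 ± 29. SERPINB2 fell by 4.55 ± 0.07 on the log2 scale. Log2 changes were -3.50 ± 0.34 for LY6K, -3.46 ± 0.26 for the fatty acid transport gene SLC27A2, -3.35 ± 0.14 for LRRC7 and -3.23 ± 0.38 for the phospholipid flippase gene ATP8B4. EVI2A and EVI2B, at -3.94 ± 0.22 and -3.78 ± 0.17, lie inside NF1 on its opposite strand. C12orf75-AS1, an antisense gene, was at -3.20 ± 0.24. These 3 values are uncertain, since the strand setting of the counting is not given in the sources used here. The smallest p among rising genes belonged to TGFBI, a TGF-beta-induced matrix gene that rose from 25920 ± 889 to 342288 ± 12399, and PMEPA1, FN1 and COL5A1 were also among the 5 with the smallest p. After SERPINB2, the smallest p among falling genes belonged to SFRP1, which encodes a secreted Wnt modulator and fell from 34385 ± 900 to 7636 ± 258. The claudin gene CLDN11 followed with a fall from 11872 ± 395 to 1831 ± 122. Next came AHNAK, from 155591 ± 6221 to 45244 ± 2320, and CITED2, from 5553 ± 70.4 to 749 ± 31.3. AHNAK had the highest value among the genes of the table in each PBS library.

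**Figure D1:**
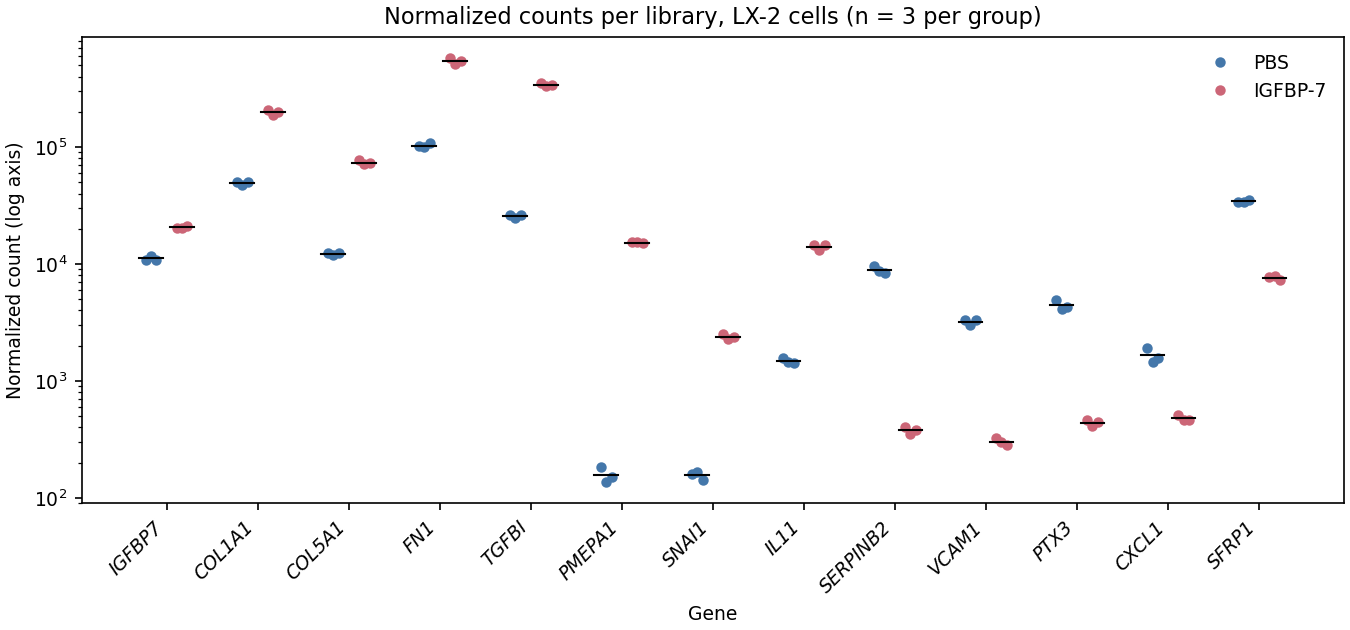
Normalized counts (log axis) of 13 genes in each of the 3 PBS and 3 IGFBP-7 libraries, with 1 point per library and a bar at the group mean. The libraries of the 2 groups do not overlap for any of these genes. Apart from IGFBP7, the genes were named by rules that require or favour such separation. FN1 lies at 102918 ± 4088 in PBS and 544971 ± 32799 with IGFBP-7 (mean ± SD).

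Of the 22 tested genes of the stellate activation list, 16 rose and 6 fell, with a median log2 change of 1.17. With scaling to the library total 15 rose and 6 fell, with a median of 1.03. TGFB1, which encodes the cytokine TGF-beta, rose from 5979 ± 227 to 24164 ± 1215, COL1A1 from 49614 ± 1794 to 198928 ± 8843, and the tropomyosin gene TPM1 from 25582 ± 325 to 83739 ± 2959. The list lay above the other genes (camera adjusted p = 7.97e-26; adjusted p = 0.386 with an estimated correlation). Here and below, counts adjusted over the list alone were the same as those over all genes tested unless both are given. Among 20 collagens, 16 rose and 4 fell, with a median of 1.45 (camera adjusted p = 2.50e-20; adjusted p = 0.386 with an estimated correlation). With scaling to the library total 15 rose and 4 fell, with a median of 1.30. COL5A1 rose from 12285 ± 371 to 73632 ± 2783, COL6A3 from 5022 ± 368 to 29569 ± 1554 and COL27A1 from 1820 ± 68.2 to 9049 ± 226.

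Matrix glycoproteins and proteoglycans moved both ways, with 16 of 29 genes higher, 8 lower and 5 not passing, against 16 higher and 9 lower when adjusted over the list alone. Their median log2 change was 0.31, or 0.17 with scaling to the library total (camera adjusted p = 2.40e-11; adjusted p = 0.448 with an estimated correlation). THBS1, the thrombospondin gene, rose by 1.90 ± 0.04 and SPARC, which encodes osteonectin, by 1.49 ± 0.04. Of 26 matrix remodelling enzymes and inhibitors, 13 rose, 8 fell and 5 did not pass, with 13 higher and 9 lower when adjusted over the list alone. SERPINE2, a protease inhibitor gene, rose by 1.76 ± 0.04 and the collagen cross-linking enzyme gene LOX by 1.91 ± 0.05, while the interstitial collagenase gene MMP1 fell from 19830 ± 1072 to 4571 ± 131. The list's median was 0.13, moved to 0.081 with quantile normalization and flipped to -0.012 with scaling to the library total. Its camera adjusted p was 1.81e-06, and adjusted p = 0.416 with an estimated correlation.

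TGF-beta response genes rose in 24 of 27 cases and fell in 3, with a median log2 change of 0.78 (camera adjusted p = 1.19e-44; adjusted p = 0.302 with an estimated correlation). With scaling to the library total 20 rose and 3 fell, with a median of 0.63. Besides PMEPA1 and TGFBI, the AP-1 gene JUNB rose from 1690 ± 165 to 11761 ± 218. Of 17 mesenchymal transition regulators and junction genes, 10 rose, 6 fell and 1 did not pass, with a median of 0.62 (camera adjusted p = 7.95e-05; adjusted p = 0.386 with an estimated correlation). SNAI1, which encodes the repressor Snail, rose from 156 ± 13.5 to 2384 ± 117, the N-cadherin gene CDH2 from 6018 ± 54.4 to 12759 ± 18.6, the integrin gene ITGA5 from 15076 ± 880 to 30239 ± 1413, and CDH11 by 2.28 ± 0.11 on the log2 scale. YAP and TEAD response genes fell in 19 of 23 cases and rose in 4, with a median of -0.75 (camera adjusted p = 1.12e-10; adjusted p = 0.386 with an estimated correlation). F3, which encodes tissue factor, fell from 8347 ± 186 to 1471 ± 56.2, the LIM-domain gene AJUBA from 8321 ± 82.9 to 2605 ± 166 and the receptor kinase gene AXL from 31204 ± 809 to 16286 ± 810.

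In the IGF axis, 3 of 17 tested genes rose, 10 fell and 4 did not pass, with a median of -0.32 (camera adjusted p = 0.00836; adjusted p = 0.448 with an estimated correlation). IGFBP5 fell from 4995 ± 321 to 1176 ± 106, IGFBP6 from 3494 ± 35.8 to 1774 ± 61.1, and STC2, which encodes an inhibitor of IGF binding protein cleavage, from 3428 ± 227 to 1166 ± 35.2. HTRA1, which encodes a secreted protease that cleaves IGF binding proteins, rose from 1960 ± 43.9 to 4070 ± 336.

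Cytokines and chemokines moved in opposite directions, with 8 of 27 genes higher, 15 lower and 4 not passing. IL11, a cytokine gene of the interleukin 6 family, rose from 1492 ± 77.7 to 14029 ± 732, LIF of the same family from 430 ± 10.4 to 2368 ± 147, and the chemokine gene CXCL12 from 6153 ± 58.0 to 21519 ± 859. CXCL1, which encodes a neutrophil chemokine, fell from 1651 ± 246 to 479 ± 28.2. The list's median was -0.62 and its mean -0.37, while the camera direction was up (camera adjusted p = 0.327), so the list did not stand apart. With a filter at a mean of 100 normalized counts it passed in the upward direction (camera adjusted p = 0.0401, within 0.00841 to 0.771 over its alternatives). NF-kappaB response genes fell in 16 of 23 cases, rose in 5 and did not pass in 2, with 6 higher and 16 lower when adjusted over the list alone. BIRC3, which encodes an inhibitor of apoptosis, fell from 3444 ± 159 to 1128 ± 72.1, and IL1B from 2660 ± 373 to 1116 ± 134. The NF-kappaB list had a median of -0.46 (camera adjusted p = 4.90e-05; adjusted p = 0.386 with an estimated correlation). Chosen after their values were seen, CXCL8, a member of both lists, had a log2 change of -1.15 ± 0.08, IL6 one of 0.84 ± 0.08 and CCL2 one of 1.01 ± 0.10, all with a limma adjusted p under 0.05.

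Secreted growth factors were also divided, with 16 of 32 higher, 13 lower and 3 not passing, and with 16 higher and 14 lower when adjusted over the list alone. VEGFA, the main angiogenic factor gene, rose from 2197 ± 74.6 to 9696 ± 441, the activin subunit gene INHBA from 782 ± 26.9 to 3537 ± 203, and ANGPTL2 from 2113 ± 38.3 to 6433 ± 411. The neurotrophin gene BDNF fell from 1292 ± 80.4 to 190 ± 21.5. The median was 0.13, or -0.012 with scaling to the library total, the mean was -0.042 and the camera direction was up (camera adjusted p = 0.196). Interferon response genes fell in 26 of 34 cases, rose in 2 and did not pass in 6, with a median of -0.37 (camera adjusted p = 0.00281; adjusted p = 0.491 with an estimated correlation). The membrane protein genes IFITM1, IFITM2 and IFITM3 had log2 changes of -1.18 ± 0.09, -1.18 ± 0.10 and -0.59 ± 0.06, which are uncertain because these 3 genes are close paralogs. IFI44 rose by 0.78 ± 0.08.

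**Figure D2:**
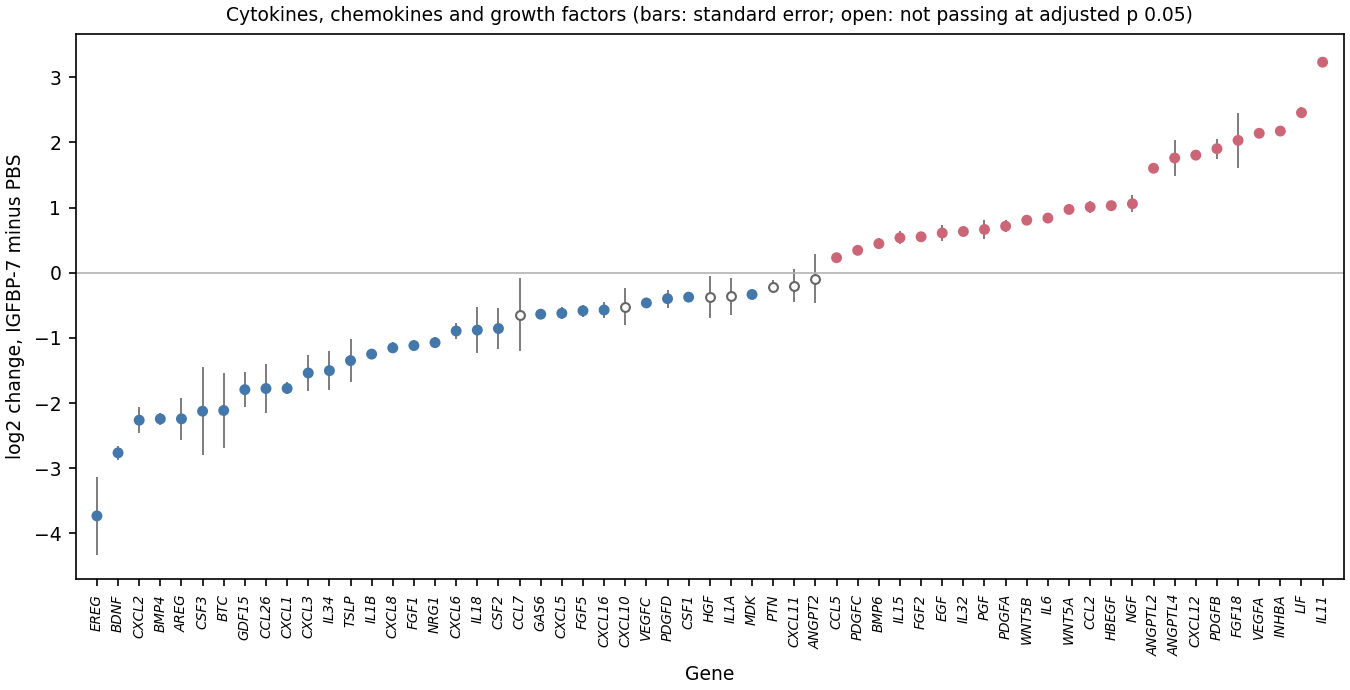
Log2 changes (IGFBP-7 minus PBS, points) with limma standard errors (bars) of the 59 tested genes of the cytokine and growth factor lists, in order of size. Red points mark the 24 genes that rose, blue points the 28 that fell and open points the 7 that did not pass; IL11 at 3.23 and LIF at 2.46 stand at the upper end.

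Of 39 proliferation genes, 8 were tested, 5 of which rose, 2 fell and 1 did not pass, with a median of 0.22 (camera adjusted p = 0.708). With scaling to the library total 2 rose and 2 fell, with a median of 0.074. The cyclin gene CCNA2 rose by 0.35 ± 0.05 and the replication gene MCM10 by 0.29 ± 0.06, and the helicase subunit genes MCM2 and MCM5 were at -0.30 ± 0.05 and -0.27 ± 0.05. The other members, among them most mitotic genes, were not analysed here. In the p53 response and cell-cycle arrest list, 7 of 25 genes rose, 13 fell and 5 did not pass, with a median of -0.19, or -0.33 with scaling to the library total (camera adjusted p = 0.417). PLK2, a stress-responsive kinase gene, fell from 6347 ± 186 to 1623 ± 52.6 and GADD45A from 3214 ± 137 to 1562 ± 178, whereas GADD45B rose by 1.41 ± 0.07 and TP53I3 by 1.42 ± 0.07. Immediate early and MAPK feedback genes rose in 8 of 28 cases, fell in 16 and did not pass in 4, with 8 higher and 17 lower when adjusted over the list alone. FOSL1, an AP-1 gene, fell from 12168 ± 530 to 3086 ± 146 and PHLDA1 from 6306 ± 187 to 2028 ± 51.2, while EGR2 rose from 31.3 ± 12.1 to 1357 ± 72.4. The list's median was -0.51 (camera adjusted p = 0.186). With DESeq2 on recovered reads it passed (camera adjusted p = 0.0484, within 0.000793 to 0.434 over its alternatives).

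Hypoxia and glycolysis genes rose in 21 of 26 cases, fell in 4 and did not pass in 1, with a median of 0.41, or 0.27 with scaling to the library total (camera adjusted p = 6.28e-06; adjusted p = 0.302 with an estimated correlation). P4HA1 and PLOD2, which encode collagen hydroxylases, rose from 1892 ± 33.8 to 5013 ± 194 and from 10443 ± 229 to 20727 ± 809, and the vasoactive peptide gene ADM fell from 2220 ± 94.6 to 539 ± 53.2. Cholesterol synthesis genes rose in 17 of 23 cases, fell in 5 and did not pass in 1, with a median of 0.35, or 0.22 with quantile normalization and 0.20 with scaling to the library total (camera adjusted p = 0.0235; adjusted p = 0.434 with an estimated correlation). That call was lost with quantile normalization (camera adjusted p = 0.205), with scaling to the library total (0.144) and with a filter at a mean of 100 (0.0535), within 0.00318 to 0.434 over its alternatives. INSIG1, a sterol-sensing regulator gene, rose from 10584 ± 738 to 20128 ± 238 and the synthase gene HMGCS1 from 18600 ± 1104 to 26494 ± 451, and the lanosterol synthase gene LSS fell from 12931 ± 133 to 7386 ± 201. Fatty acid synthesis and lipid storage genes rose in 8 of 19 cases, fell in 9 and did not pass in 2. GPAM, which encodes the first enzyme of glycerolipid synthesis, rose from 862 ± 66.3 to 2825 ± 44.9 and the desaturase gene SCD from 26435 ± 1373 to 40371 ± 1216. The median of this list was -0.20, or -0.34 with scaling to the library total, the mean 0.069 and the camera direction up (camera adjusted p = 0.338).

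Unfolded protein and integrated stress response genes rose in 16 of 25 cases, fell in 8 and did not pass in 1, with a median of 0.31 (camera adjusted p = 0.188). With quantile normalization 14 rose and the median was 0.18, and with scaling to the library total 14 rose and it was 0.16. The chaperone genes HSPA5 and HSP90B1 rose by 0.76 ± 0.04 and 0.52 ± 0.04, PPP1R15A fell from 4177 ± 72.0 to 1756 ± 114 and the cystine transporter gene SLC7A11 from 3841 ± 365 to 1597 ± 101. In the NRF2 and antioxidant response, 6 of 20 genes rose, 10 fell and 4 did not pass, with 6 higher and 11 lower when adjusted over the list alone. The thioredoxin reductase gene TXNRD1 fell from 25117 ± 363 to 9823 ± 247, and GCLM, a glutathione synthesis gene, rose from 2770 ± 277 to 6182 ± 348. FTH1, the ferritin heavy chain gene, fell by 0.59 ± 0.04 and has processed pseudogenes that can share its reads. The NRF2 list's median was -0.33 (camera adjusted p = 0.0471; adjusted p = 0.386 with an estimated correlation). The call was lost without PBS replicate 1 (camera adjusted p = 0.0639), PBS replicate 2 (0.0650), PBS replicate 3 (0.0597) or IGFBP-7 replicate 2 (0.0578) and under 4 other processing settings, within 0.000135 to 0.386 over its alternatives. Of 32 oxidative phosphorylation genes 7 were tested, 4 of which rose, 1 fell and 2 did not pass. UQCRC1, of complex III, rose by 0.26 ± 0.05 and SDHA, of complex II, fell by 0.31 ± 0.04. The median was 0.18 (camera adjusted p = 0.758), and with scaling to the library total 1 gene rose and 2 fell, the median was 0.035 and the camera direction turned down.

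Stellate quiescence genes rose in 2 of 16 cases, fell in 7 and did not pass in 7, with a median of -0.49 (camera adjusted p = 0.150). RELN, which encodes the matrix protein reelin, fell from 529 ± 44.0 to 71.8 ± 19.7 and the lipid droplet gene PLIN2 from 1056 ± 54.3 to 661 ± 5.98. ECM1 fell by 0.50 ± 0.05, and the retinoic acid receptor gene RARA rose by 0.59 ± 0.07.

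Markers of other liver cell types moved in both directions. Of 4 tested hepatocyte markers, too few for a list test, 1 rose and 3 did not pass. The asialoglycoprotein receptor gene ASGR1 rose from 118 ± 14.7 to 173 ± 34.1, a call that was lost without PBS replicate 3 (limma adjusted p = 0.0520), without IGFBP-7 replicate 2 (0.113) and with scaling to the library total (0.0647), within 0.00422 to 0.113 over its alternatives. SERPINA1 stood at 252 ± 26.5 in PBS and 227 ± 24.2 with IGFBP-7, HPX at 16.1 ± 2.94 and 26.9 ± 9.22, and AFP at 25.0 ± 11.4 and 28.6 ± 7.04. Among 9 endothelial markers, 3 rose, 2 fell and 4 did not pass. STAB1 rose from 240 ± 31.8 to 517 ± 36.9 and TEK from 138 ± 34.5 to 224 ± 35.1, and EGFL7 and TIE1 were at -0.33 ± 0.06 and -0.29 ± 0.06. The endothelial median was -0.023, or 0.069 with quantile normalization and -0.16 with scaling to the library total, the mean was 0.14 and the camera direction was up (camera adjusted p = 0.870). Of 5 macrophage and leukocyte markers, CD14 fell from 399 ± 11 to 86.0 ± 16.6, CD68 from 2863 ± 53.3 to 1466 ± 135 and CD74 from 242 ± 12.8 to 170 ± 17.8, while CSF1R rose from 56.5 ± 8.05 to 293 ± 44.3. In all 1 rose and 4 fell, with a median of -0.86 (camera adjusted p = 0.200). Of 6 epithelial and cholangiocyte markers, 3 rose, 1 fell and 2 did not pass, with 4 higher and 1 lower when adjusted over the list alone. The keratin genes KRT8 and KRT18 rose by 0.66 ± 0.04 and 0.43 ± 0.05, SOX9 rose by 0.49 ± 0.08 and MUC1 fell by 0.84 ± 0.20. The epithelial median was 0.34, or 0.20 with scaling to the library total (camera adjusted p = 0.189).

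Of 13 tested cytosolic ribosomal protein genes, 12 rose and 1 did not pass, and all 13 were higher when adjusted over the list alone. RPS23 rose by 0.36 ± 0.04 and RPLP0 by 0.30 ± 0.04 on the log2 scale, values that are uncertain because ribosomal protein genes have many processed pseudogenes. The call of RPLP0 was lost with quantile normalization, where its log2 change was 0.016 (limma adjusted p = 0.657, within 1.69e-14 to 0.657 over its alternatives). The list's median was 0.28, or 0.14 both with quantile normalization and with scaling to the library total (camera adjusted p = 0.00966; adjusted p = 0.434 with an estimated correlation). Its call was lost with quantile normalization, where 8 genes rose (camera adjusted p = 0.248), and with scaling to the library total, where 9 rose (0.0897), within 0.00374 to 0.434 over its alternatives. Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, fell in 1 of 16 cases and did not pass in 15, and 2 fell with scaling to the library total. H2BC5 stood at 435 ± 18.8 and 373 ± 32.5 and did not pass, but passed as lower with that scaling (limma adjusted p = 0.00575) and without IGFBP-7 replicate 1 (0.0470), within 0.00575 to 0.225 over its alternatives. H2BC21 fell by 0.36 ± 0.11, a call that was lost without PBS replicate 3 (limma adjusted p = 0.0665, within 0.000114 to 0.0665 over its alternatives). H2AC6 stood at 856 ± 86.0 in PBS and 853 ± 56.0 with IGFBP-7. The histone median was 0.0082, or -0.016 with upper-quartile scaling and -0.13 with scaling to the library total, and the camera direction was down (camera adjusted p = 0.870). Mitochondrially encoded genes were not analysed here.

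**Figure D3:**
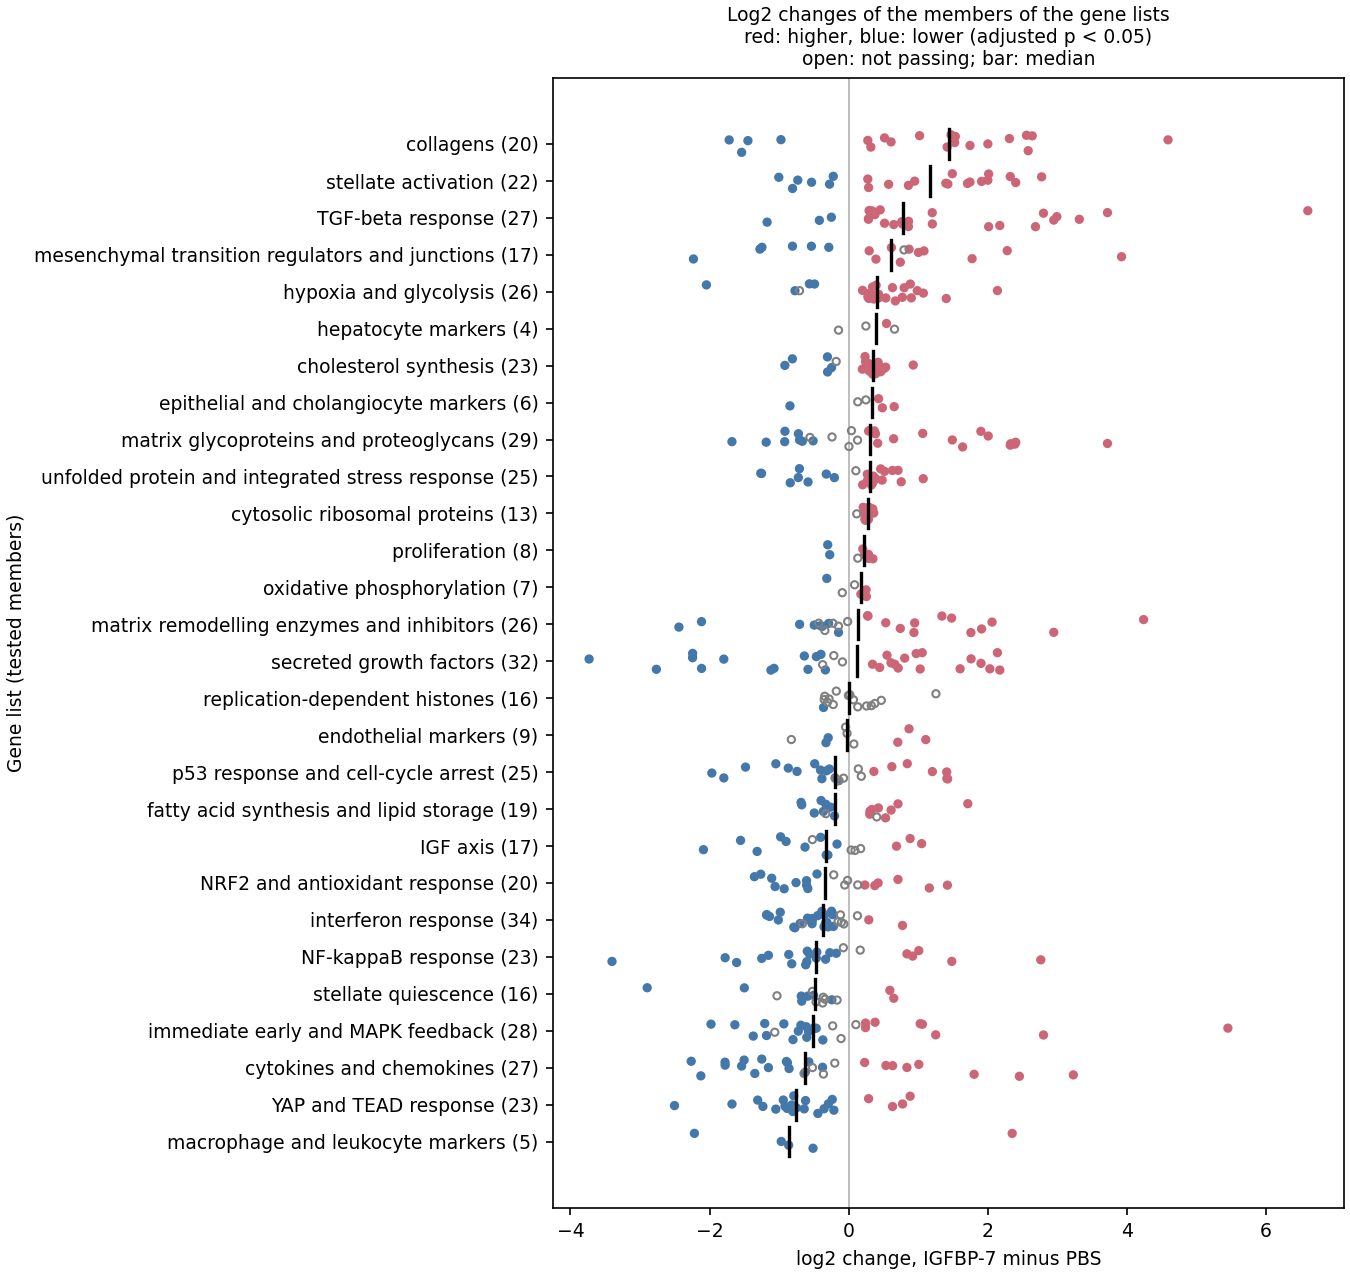
Log2 changes (IGFBP-7 minus PBS) of the tested members of the gene lists, 1 row per list with the number of tested members, 1 point per gene and a black bar at the median. Collagens at a median of 1.45 stand at the top and macrophage and leukocyte markers at -0.86 at the bottom. The medians of matrix remodelling genes and growth factors (both 0.13) and of histones (0.0082) flip below 0 with scaling to the library total, the histone median also with upper-quartile scaling, and the endothelial median (-0.023) flips above 0 with quantile normalization.

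Of the 27 lists tested with camera, 14 passed, 9 higher and 5 lower. When camera estimated the correlation per list, 0 passed and 3 had an unadjusted p under 0.05, and with fry 24 passed. The list calls therefore rest on the preset correlation of 0.01 and the degrees of freedom that go with it, while the counts of members rest on the tests of single genes.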

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

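Scaling to the library total and edgeR on recovered fragments were chosen after the data were seen. The count of 7192 changed genes lay between 6072 (adjusted p under 0.01) and 7827 (under 0.1), and between 6673 and 6841 with 1 library left out. With a fold of at least 1.5 it was 2701. With scaling to the library total 6608 genes changed, 5903 of them shared with the 7192. The IGFBP7 transcript kept its direction and its call in all alternatives, with log2 changes of 0.75 to 0.93. Of the 120 named genes past the threshold, 114 kept their call in each of the 17 alternatives in which they were tested (genes with a mean under 100 drop out with the filter at 100), and ASGR1, CYC1, H2BC21, RPLP0, RPSA and UQCRB lost it in at least 1. AFP and H2AC6, which did not pass, ranged from -0.057 (without PBS replicate 3) to 0.58 and from -0.081 to 0.064 (without PBS replicate 3) with 1 library left out. H2AC6 also turned sign with quantile normalization (0.012). No shared deviation of same-numbered libraries was seen: deviations from the group means correlated at -0.045, 0.012 and -0.049 for these pairs. Such values cannot show whether the libraries were handled in pairs. With the replicate number as a block 7177 genes and 13 lists passed. Camera passed 12 to 15 lists under other scalings, filters, tools and pseudocounts. With an estimated correlation 0 passed, with adjusted p of 0.302 (TGF-beta, hypoxia), 0.386 (stellate activation, collagens, NF-kappaB, YAP and TEAD, mesenchymal, NRF2), 0.416 (matrix remodelling), 0.434 (cholesterol, ribosomal), 0.448 (matrix glycoproteins, IGF axis) and 0.491 (interferon), and the direction of the cytokines turned (0.771). That run estimates a correlation per list and uses only the residual degrees of freedom of the libraries. With fry 24 passed, as it does not set a list against other genes: quiescence joined at 0.00212, cytokines at 0.00841, growth factors at 0.000877, proliferation at 0.0473, p53 at 0.0160, immediate early at 0.000793, unfolded protein response at 0.00113, fatty acid synthesis at 0.0216, macrophages at 0.000871 and epithelial markers at 0.00103. Among the lists that joined, the fry direction was up for cytokines and fatty acid synthesis, although their medians were -0.62 and -0.20. For the others it went with the median. With camera, cytokines passed with a filter at a mean of 100 (0.0401) and immediate early genes with DESeq2 (0.0484). Cholesterol synthesis was lost with quantile normalization (0.205), the library total (0.144) and the filter at 100 (0.0535), and ribosomal proteins with quantile normalization (0.248) and the library total (0.0897). NRF2 was lost with the filter at 100 (0.0635), edgeR on fragments (0.0671), a pseudocount of 5 (0.0551) and the replicate block (0.0535), and ranged from 0.0285 to 0.0650 with 1 library left out. Among lists that did not pass, the direction turned for oxidative phosphorylation with the library total (0.978), endothelial markers without a filter (0.985) and with DESeq2 (0.952), and histones with quantile normalization (0.997) and the library total (0.864). Beyond the construction of the list tests and of the fold threshold, the cause was not tested. Depth limits genes near the floor of 2.54 to 3.20 normalized counts.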

Other observations

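The tests of splits, of endotoxin and of the source of TGF-beta were chosen after the results were seen, and those of depth, abundant genes and GC content before. HES1, a transcription factor gene that Notch signalling switches on, rose from 121 ± 38.3 to 1609 ± 17.9 normalized counts (mean ± SD, n = 3 per group), and the Notch ligand gene JAG1 from 1628 ± 84.4 to 8133 ± 375. In a list of 16 Notch pathway genes written after HES1 was seen, 12 were tested. Of these, 8 rose, 0 fell and 4 did not pass in limma. The other risers were HEYL (log2 change 2.41), HEY1 (2.19), NOTCH3 (1.46), LFNG (1.41), NOTCH4 (0.92) and HES4 (0.77). Those not passing were the ligand genes JAG2 (-0.55, limma adjusted p = 0.0544), DLL1 (-0.29) and DLL4 (-0.27), and NRARP (0.34). Because the list was written after its values were seen, whether these genes stand apart from others was not tested.

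In a list of genes that process and secrete collagen, also written after the values were seen and not tested for standing apart, 19 of 22 tested genes rose, and P4HA3, COLGALT2 and ADAMTS14 fell. BMP1, which encodes a procollagen proteinase, rose from 4784 ± 82.6 to 10248 ± 363, the collagen chaperone gene SERPINH1 from 11173 ± 75.6 to 16251 ± 230, and P4HA2, a collagen prolyl hydroxylase gene, from 8680 ± 325 to 15119 ± 827. P4HA1, P4HA2 and PLOD2 are also members of the hypoxia list.

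The first pattern weighed is that 7192 of 11872 tested genes changed. The IGFBP-7 libraries held more recovered reads on the genes of the table. After thinning every library to the smallest, 6984 of the 7192 were still shared with the same sign. A few abundant genes took more of the counts, with the 50 most abundant at 11.2% to 11.6% in PBS and 16.0% to 16.9% with IGFBP-7, yet 6711 were shared after removing them and rescaling. After the trend on GC content and length was removed, 6764 of the 7173 changed genes with values were shared, so these 3 explanations do not account for most of the calls. The 6 libraries make 10 splits into 3 and 3. In limma the real split gave 7192 genes and the highest other 0, with up to 109 at an unadjusted p under 0.05. Each other split mixes PBS and IGFBP-7 libraries, which widens the spread within its groups, so the 0 is no baseline for data without an effect. Other tools were not run on the splits, and so few splits cannot give a share under 0.05.

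The second pattern is that TGF-beta response genes rose, in 24 of 27 cases, and in 20 with scaling to the library total. Endotoxin carried with a recombinant protein would raise NF-kappaB targets, and of the 23 tested NF-kappaB genes 16 fell and 5 rose, IL6 (0.84) and CCL2 (1.01) among them, with a median of -0.46 and a 95% bootstrap interval over members of -0.62 to -0.18. With an estimated correlation between members the list does not pass (camera adjusted p = 0.386). As 0 of the 27 lists pass in that run, it cannot decide the question. The 16 falls go against endotoxin as the whole cause, while the 5 rises do not, and endotoxin as the whole or a part of the cause stays open. Active TGF-beta is another candidate source, either brought by the protein preparation or made by the cells, whose TGFB1 transcript rose by 2.01 on the log2 scale. These sources and a direct effect of IGFBP-7 cannot be told apart, because the design holds no sample with TGF-beta signalling blocked and no other protein preparation.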
